A study of Homo sapiens with 75 samples.

How the data were processed

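RNA from 75 samples of primary acute lymphoblastic leukaemia cells was measured on 1-colour Affymetrix expression arrays, 1 array per sample. Per the labels, all samples belong to a single kind of source material. The series title names VCR-sensitive B-lineage leukaemia, VCR being the usual abbreviation of vincristine. The labels used here place no sample in a response group or a genetic subtype, so 1 group was analysed and no contrast between groups was made. The deposited values are array intensities, a linear signal per probe set that, per the labels, the authors computed with the Affymetrix statistical algorithm and scaled by a single factor per array over all probe sets to a target of 500. The software version is not given in the sources used here. Each array's scale factor, background, noise and pixel variation were taken from the labels. The number of arrays limits the precision.

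The table held 22283 probe sets, of which 68 were control probe sets. In the platform's annotation, 19071 probe sets were listed with 1 gene, 1043 with several and 2169 with none, and only probe sets with 1 gene were named. The symbols of 19059 probe sets were updated through Entrez identifiers with the gene table of the GRCh38.p14 assembly, and 12 were kept as listed. That assembly was used for names, for the chromosome of a gene and for the order of neighbouring genes only, and no coordinate is given. Left out for privacy were 118 probe sets, those of XIST, Y-linked genes, HLA and KIR genes, immunoglobulin variable genes and genes whose level follows a common germline deletion.

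Values were used as log2(value + 50). A probe set counted as measured when its mean deposited value over the 75 arrays was at least 500, which held for 5653 probe sets of 3581 genes, out of 11889 genes on the array. Where a gene had several probe sets, that of the highest mean stood for the gene. Differences on the log2(value + 50) scale understate changes of dim genes. No sample was excluded. All 2775 pairs of arrays were compared for identical values.

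The genes were grouped in 27 lists fixed before the data were examined: B lineage, pre-B receptor, lymphoid progenitor, stem and progenitor, T cell, natural killer, monocyte, neutrophil granule, erythroid, megakaryocyte and platelet, plasma cell, stroma and endothelium, cell cycle, tubulin, microtubule-associated, drug transport and metabolism, targets of other drugs, apoptosis, ribosomal protein, actin cytoskeleton, interferon response, immediate early, heat shock, glycolysis, cholesterol synthesis, subtype-linked and housekeeping. The main tests, the rule for named genes and all alternatives except 1 were also set before the data were examined. A list with at least 4 measured members was tested, which 22 lists had.

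Co-variation of a list was the mean pairwise Spearman correlation of its members over the arrays, set against 10000 random lists of the same size matched on mean level in 20 quantile bins (one-sided). The spread of a list was the median over its members of log2(SD / trend SD), with the trend from a lowess curve of SD on mean, set against the same random lists (two-sided). A list score was the mean of its members' z-scores. Planned relations between list scores numbered 18, of which 13 had enough measured members on both sides. Each was given as Pearson's r and Spearman's rho with 100000 permutations (two-sided), and r was computed again without the 2 arrays farthest from the median of the first score. A score was called clustered when a mixture of 2 normal components gained at least 10 in BIC over 1 component with means at least 4 SD apart. Relations of a clustered score were computed within clusters of at least 6 arrays. The relations were also computed in the 37 arrays of lower and the 38 arrays of higher scale factor. B-lineage with T-cell genes had too few measured members at lower scale factor and was computed only at higher. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05 within each family of tests.

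Gene-wise tests used limma 3.58.1 in R 4.3.3. Unusual spread was tested with a one-sided F test of each probe set's variance against the robust mean-variance trend. The trend and the spread of variances around it were fitted to these same probe sets. Genes that varied with a list score were found from the limma slope of log2(value + 50) per SD of the score, with log2 scale factor as a covariate and the members of the list left out. Lists were tested along a score with camera, with an estimated inter-gene correlation and with a preset one of 0.01. Genes varying with log2 scale factor were tested the same way without a score. Each score was also shuffled 100 times among the arrays. Shuffling breaks every link between a score and the arrays, so it cannot show that a count is particular to the list. Scores of random lists were not tested. Named genes are the members of the lists, the 20 genes of largest F, the 8 genes of largest positive and of largest negative slope past the threshold for each score, and the 10 genes of lowest spread relative to the trend. Other named genes are said to have been chosen after their values were seen. The remaining computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. Upper-tail shares carry Wilson intervals at a confidence level of 95%, which cover counting error only.

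The tests were tested on simulated data built on the real arrays' levels. In the test of spread over 5653 probe sets, none of 67 probe sets with their SD raised by a factor of 2 was called. It called 2 of 67 with a factor of 4 and 60 of 66 with a factor of 8, with 2 false calls among 5453 unchanged probe sets. Variances of the unchanged probe sets were drawn from the spread fitted to the real data. In the slope test for the cell-cycle score over 3566 genes, 59 of 100 genes with a slope of 0.25 and 100 of 100 with a slope of 0.5 were called, with 9 false calls among 3366 unchanged genes. In the co-variation test over 3581 genes, 20 of 20 simulated lists of 10 genes with a loading of 0.3, 20 of 20 with a loading of 0.6 and 0 of 20 with no loading were called. The simulated lists had a mean rho of 0.0855 at a loading of 0.3 and -0.0059 with no loading. Matched random lists of the real ribosomal protein list averaged 0.168. The real housekeeping list, at 0.0732 over 14 members, was not past the co-variation test (adjusted p = 0.0689). The simulated counts therefore do not give the power of that test on the real, correlated genes.

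Alternatives were pseudocounts of 1 and 200, no minimum and a minimum of 1000 on the mean value, quantile normalization between arrays, scale factor alone or with the 3'/5' signal ratio of GAPDH as covariates or no covariate, leaving out 3 arrays of background above 60, each of the 2 sets of arrays by scale factor, the mean of all probe sets of a gene, leaving out the 10407 probe sets whose identifier ends in _s_at or _x_at (probes that can match several transcripts), a non-robust variance trend, and a threshold of 8 times the median for the upper tail. Leaving out 1 array with high T-cell markers was added after seeing the data. The p-values measure the spread between these samples, and the labels do not say more on how independent the samples are.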

Results

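Gene expression was measured in 75 samples of primary acute lymphoblastic leukaemia cells, 1 array each, all of 1 group. The series title names B-lineage leukaemia sensitive to vincristine, a drug that binds tubulin and blocks the mitotic spindle. The 75 samples may thus be selected for sensitivity, which no label gives per sample. Response to the drug and genetic subtype were not analysed here, because the labels used here give neither for a sample. The question the data could address was therefore which genes and gene groups differed from sample to sample, and which of them varied together. Array scale factors ran from 9.87 to 78.1 (39.3 ± 16.8, mean ± SD, n = 75), and the background average had a median of 40.2 with 3 arrays above 60. The median signal of an array lay between 169.7 and 277.7, and the 3'/5' signal ratio of GAPDH, a measure of RNA integrity, between 0.692 and 1.46. Pearson correlations between arrays ranged from 0.719 to 0.900 with a median of 0.817 over 2775 pairs, and no pair held identical values.

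B-lineage genes were measured across the series. CD79A and CD79B, which encode the signalling chains of the B-cell receptor, had mean signals of 6683 ± 3876 and 2270 ± 1643 (SD, n = 75), and PAX5, the transcription factor that commits cells to the B lineage, had 2896 ± 1397. In the pre-B receptor list, IGLL1, which encodes a part of the surrogate light chain, had a mean of 3702 ± 4603 with a 43.7-fold range between the 10th and 90th percentiles of the arrays, and VPREB1, its partner, had 4371 ± 3823 with a 23.9-fold range. Among progenitor genes, DNTT, the terminal transferase of early lymphoid cells, spanned 375 to 6340 between those percentiles, and MME, which encodes the surface antigen CD10, spanned 101.6 to 3273 around a mean of 1388 ± 1561. CD34 had 947 ± 1254 and FLT3, a receptor kinase of progenitors, 969.8 ± 929.5.

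**Figure D1:**
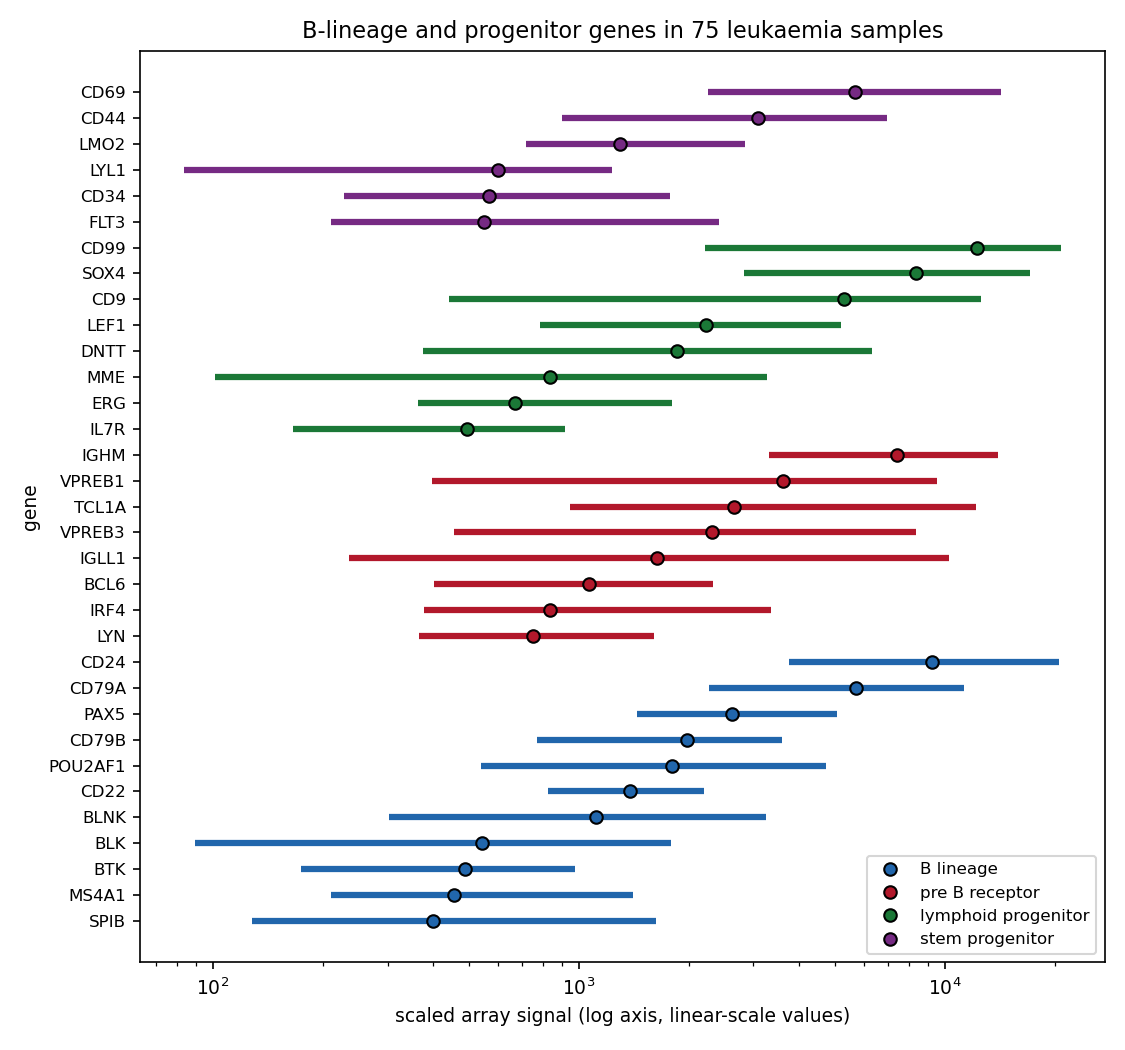
Scaled array signal (log axis) of the measured B-lineage, pre-B receptor, lymphoid progenitor and stem and progenitor genes in the 75 samples; points are medians and bars run from the 10th to the 90th percentile. The bar of IGLL1 spans a 43.7-fold range and that of CD22 a 2.66-fold range.

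Of the 14 tubulin genes on the array, whose family encodes the protein that vincristine binds, 9 were measured. TUBB had a mean signal of 16960 ± 7148 (n = 75) with a 2.63-fold range between the 10th and 90th percentiles, and TUBA1B had 33570 ± 12150 with a 2.59-fold range. TUBB6 spanned 95.3 to 2728 between those percentiles around a mean of 1054 ± 1184, and TUBB2A had an 8.85-fold range around 2020 ± 1472. Among genes of microtubule regulation, STMN1, which encodes the microtubule-destabilising protein stathmin, had 1089 ± 614 and MAPRE1, a plus-end binding protein, 5147 ± 1402. ABCB1, the multidrug transporter, had a mean below 500 and was not used, while ABCC1 had 1138 ± 561. Tubulin transcripts are nearly identical in long stretches, and 6 of the 9 tubulin probe sets are of a kind that can match several transcripts, so the signal of single tubulin genes is uncertain.

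Whole gene groups varied more between samples than genes of the same level. The spread exceeded that of matched random lists for the pre-B receptor list (median log2 excess of SD over the trend 1.24, adjusted p = 0.0022), the lymphoid progenitor list (1.11, adjusted p = 0.00147), the stem and progenitor list (0.91, adjusted p = 0.00352), the immediate early list (0.86, adjusted p = 0.00147) and the B-lineage list (0.76, adjusted p = 0.00147). Genes of red cells (0.69, adjusted p = 0.00566), T cells (0.47, adjusted p = 0.0352), the interferon response (0.39, adjusted p = 0.0088) and the actin cytoskeleton (0.29, adjusted p = 0.024) were past the threshold as well. Without 1 array with high T-cell genes, the T-cell list had 3 measured members and was not tested. Whether its call rested on that array therefore cannot be told. Ribosomal protein genes varied less than their matched random lists (-0.16, adjusted p = 0.00566). Thus 10 of the 22 tested lists were past the threshold, and the other 12 had medians from -0.07 to 0.30 with adjusted p from 0.088 for the cell-cycle list upward. Fewer lists were past without _s_at and _x_at probe sets, where fewer lists could be tested.

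Single genes with the widest spread relative to their level included members of those lists, although none passed the gene-wise test. A probe set of HBB, beta globin, had an SD 4.998 times the trend (F = 24.98, adjusted p = 0.180 in limma). KLF4, RGS1 and HCAR3 followed with 4.01, 3.83 and 3.70 times the trend, then SH3BP5 with 3.57, the chemokine gene CXCL8 with 3.56, CD9 with 3.51 and IGLL1 with 3.48. The rest of the 20 largest were AKAP12, S100A8, MARCKS, SRGN, LST1, HBD, VPREB1, NRN1, ID3, CD52, ALOX5 and EMP1, between 3.45 and 3.09 times the trend. These 20 are named for their size, since 0 of 5653 probe sets passed limma's robust test. An unadjusted p under 0.05 was found for 361, against 283 if all followed the test's fitted spread. That spread was fitted to these same probe sets, so a count near 283 and few calls were partly built in. The non-robust test also called 0, with 312 under 0.05. The simulated test called only 2 of 67 probe sets with an SD raised by a factor of 4, so 0 calls says little at these ratios. Without the minimum on the mean value, 282 probe sets were called. The steadiest genes relative to level were PPME1 (SD 0.25 on the log2 scale), N4BP1 (0.26), NFRKB (0.32), HNRNPD (0.28), MFN2 (0.28), COL11A2 (0.31), OTUB1 (0.29), PRPF31 (0.29), KDM3B (0.29) and WNT6 (0.29).

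Members of most lists rose and fell together across the samples. Red-cell genes did so most tightly, with a mean pairwise rho of 0.731 over 7 measured members and 0.927 between the globin genes HBB and HBD. Ribosomal protein genes (mean rho 0.578, 30 members) and cell-cycle genes (0.4998, 15 members) followed, and in both every pair was positively correlated. TYMS, thymidylate synthase, and MCM2, a subunit of the replicative helicase, had rho = 0.799. The interferon list (0.321, 10 members), the heat-shock list (0.288, 10 members), the immediate early list (0.276, 26 members) and the B-lineage list (0.204, 11 members) were also past the test, with rho = 0.716 for IFI44 and IRF7, 0.786 for JUN and DUSP1, and 0.568 for CD79A and CD79B. Those 7 lists had an adjusted p of 0.000314, the smallest the random lists allow here. The matched random lists of the ribosomal set averaged 0.168, and those of each other set at most 0.0474.

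A further 8 lists were past the test with larger p-values. They were the T-cell list (mean rho 0.308, 4 members, adjusted p = 0.00286), tubulin (0.184, 9 members, adjusted p = 0.00965), lymphoid progenitor (0.157, 8 members, adjusted p = 0.003), pre-B receptor (0.153, 8 members, adjusted p = 0.00788), glycolysis (0.126, 15 members, adjusted p = 0.00055), stem and progenitor (0.115, 6 members, adjusted p = 0.0497), targets of other drugs (0.0766, 9 members, adjusted p = 0.0314) and actin cytoskeleton (0.0712, 26 members, adjusted p = 0.00286). None of the 8 stayed past the threshold in every alternative. The adjusted p lay between 0.000225 and 0.0594 over 9 alternatives for the T-cell list, and over 13 alternatives between 0.00117 and 0.356 for lymphoid progenitor, 0.000825 and 0.07095 for pre-B receptor, 0.000225 and 0.154 for glycolysis, 0.0066 and 0.253 for other drug targets, and 0.000244 and 0.0734 for actin genes. Within the pre-B receptor list, IGLL1 and VPREB3 moved together (rho = 0.807), whereas VPREB3 and LYN, a kinase below the receptor, ran opposite (rho = -0.332). DNTT with MME had rho = 0.552, and FLT3 with the transcription factor LMO2 0.558. In the tubulin list, TUBB3 with TUBB4B had rho = 0.872. The tubulin list was not past without probe sets that can match several transcripts. Its mean rho there was -0.0862 over 4 members (adjusted p = 0.937, and 0.00132 to 0.937 over 13 alternatives). Loss of members and loss of shared signal cannot be told apart in that setting. Without 1 array that had high T-cell genes, the T-cell list had 3 measured members and was not tested, and the stem and progenitor list had a mean rho of 0.106 (adjusted p = 0.0683; 0.00711 to 0.162 over 11 alternatives).

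Lists not past the co-variation test were plasma cell (0.0467, adjusted p = 0.379), housekeeping (0.0732, adjusted p = 0.0689), microtubule-associated (0.0101, adjusted p = 0.517), cholesterol synthesis (0.00112, adjusted p = 0.605), apoptosis (-0.0097, adjusted p = 0.726), drug transport and metabolism (-0.0336, adjusted p = 0.726) and subtype-linked (-0.0207, adjusted p = 0.728). Inside the apoptosis list, MCL1 and PMAIP1, which encode a survival factor and its antagonist NOXA, had rho = 0.441. The natural killer, monocyte, neutrophil granule, platelet and stroma lists had 1, 3, 1, 1 and 0 measured members and were not tested at this level.

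**Figure D2:**
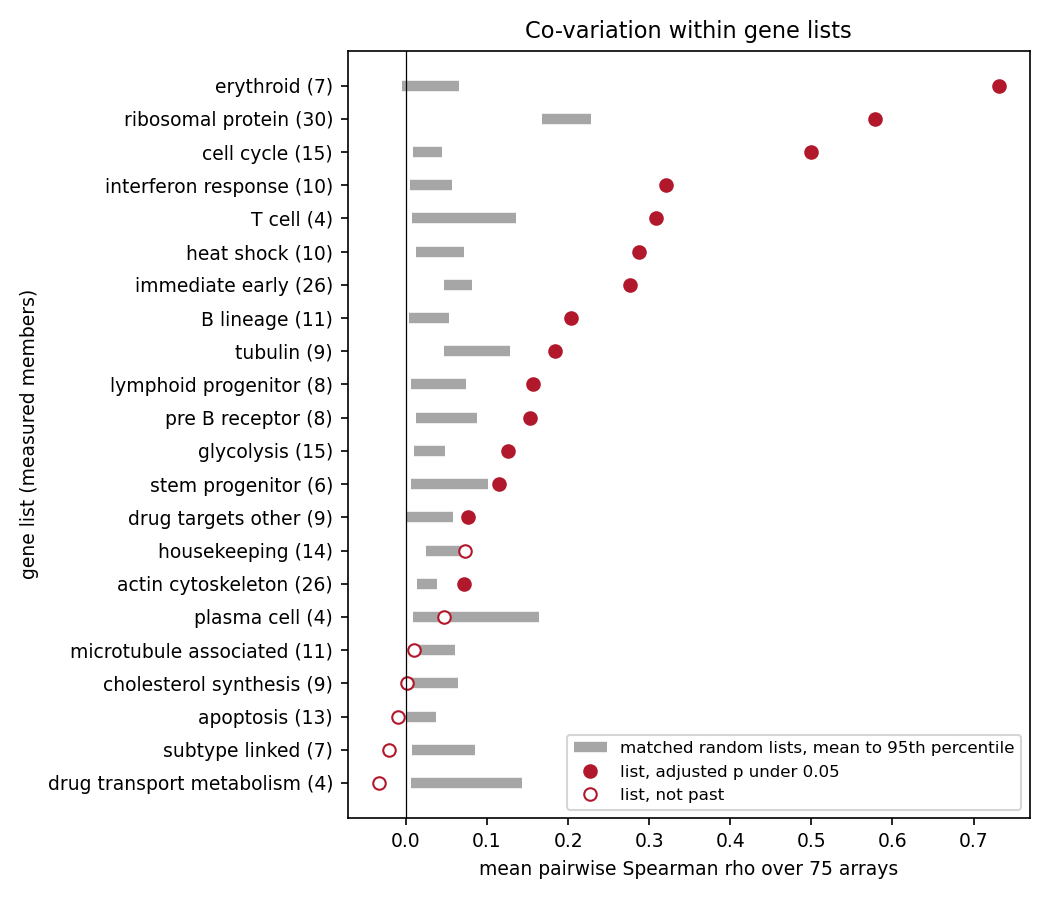
Mean pairwise Spearman rho over the 75 arrays (horizontal axis) for each tested gene list, with its number of measured members; grey bars run from the mean to the 95th percentile of matched random lists. The erythroid list lies at 0.731, the cell-cycle list at 0.4998 and the tubulin list at 0.184; filled points had an adjusted p under 0.05.

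The pre-B receptor score rose with the cell-cycle score. Their relation had r = 0.390 (permutation p = 0.00054) and rho = 0.454 (permutation p = 0.00011, adjusted p = 0.00143 over 13 relations) in 75 arrays, and r = 0.333 without the 2 farthest arrays. In the 37 arrays of lower and the 38 of higher scale factor, rho was 0.442 (adjusted p = 0.0844) and 0.428 (adjusted p = 0.0469), and over 13 alternatives the adjusted p lay between 8e-05 and 0.0844. The cell-cycle score also rose with the microtubule-associated score, with r = 0.421 (permutation p = 0.00015), rho = 0.387 (permutation p = 0.00074, adjusted p = 0.00481) and r = 0.414 without the 2 farthest arrays. That relation was 0.194 (adjusted p = 0.450) in the arrays of lower scale factor and 0.540 (adjusted p = 0.00624) in those of higher scale factor. It did not hold without probe sets that can match several transcripts (rho = 0.120, adjusted p = 0.388; 0.00156 to 0.450 over 13 alternatives).

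The pre-B receptor score was lower where the stem and progenitor score was higher. This relation had r = -0.247 (permutation p = 0.0334), rho = -0.312 (permutation p = 0.00633, adjusted p = 0.0206) and r = -0.388 without the 2 farthest arrays. Within the arrays of lower and higher scale factor rho was -0.240 (adjusted p = 0.450) and -0.410 (adjusted p = 0.0477), with an adjusted p from 0.00492 to 0.450 over 11 alternatives. Most single genes were not past: along the stem and progenitor score, IRF4 fell by 0.46 and 7 of 8 pre-B receptor genes were not past (1 fell adjusted over the list alone, adjusted p = 0.442 with an estimated correlation), and along the pre-B receptor score 0 of 6 stem and progenitor genes were past (0 adjusted over the list alone). Immediate early and heat-shock genes rose together in the 65 arrays of the larger heat-shock cluster, with r = 0.422 (permutation p = 0.00054), rho = 0.341 (permutation p = 0.00569, adjusted p = 0.0206) and r = 0.367 without the 2 farthest arrays. The 10 arrays of the smaller cluster gave r = 0.0916 (permutation p = 0.801), rho = 0.0788 (permutation p = 0.837, adjusted p = 0.837 over 14 relations) and r = 0.0166 without the 2 farthest. In 30 arrays of lower scale factor within a larger cluster rho was 0.340 (adjusted p = 0.390), and in 34 of higher scale factor 0.288 (adjusted p = 0.161), with adjusted p between 0.011 and 0.390 over 13 alternatives.

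**Figure D3:**
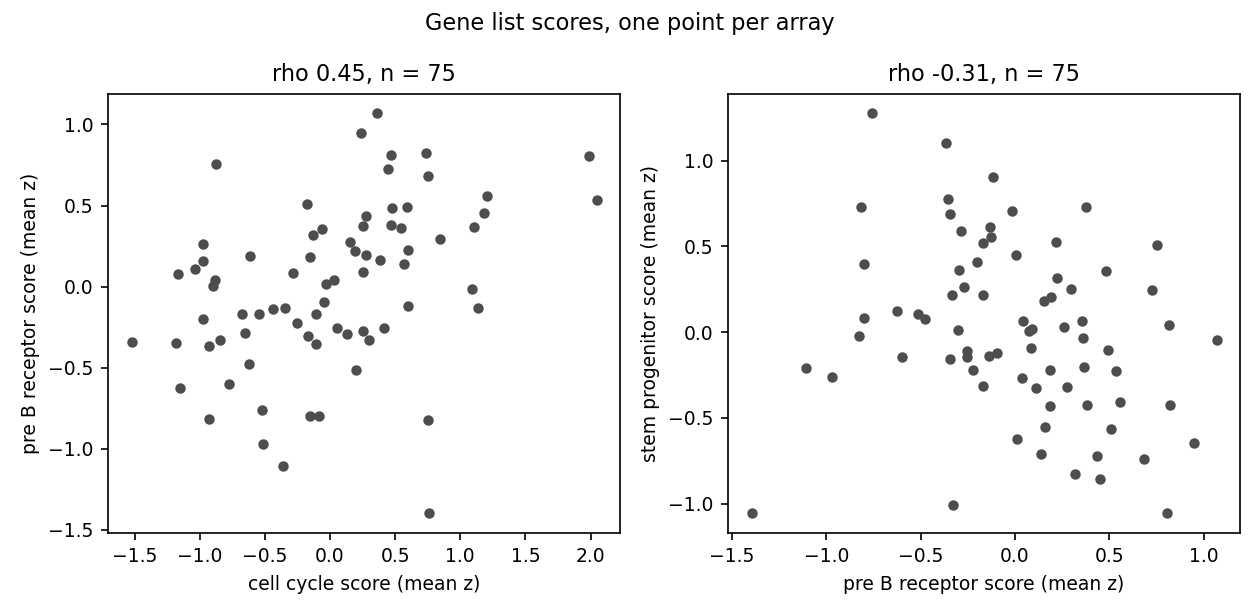
List scores (mean z-score of the members, no unit), 1 point per array, n = 75. The left panel sets the pre-B receptor score against the cell-cycle score (rho 0.454), and the right panel the stem and progenitor score against the pre-B receptor score (rho -0.312).

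None of the other 9 planned relations was past the threshold at this setting. Of these 5 are given here, and 4, all of the cell-cycle score, are not; 2 of those 4 were past it in at least 1 alternative. Cell-cycle genes with tubulin genes had r = 0.318 (permutation p = 0.00519), rho = 0.265 (permutation p = 0.0217, adjusted p = 0.0564) and r = 0.263 without the 2 farthest arrays, with rho = 0.277 and 0.235 in the arrays of lower and higher scale factor. Its adjusted p lay between 0.00992 and 0.390 over 13 alternatives. The tubulin score had rho = 0.148 with microtubule-associated genes, 0.121 with actin genes and -0.073 with drug transport genes (adjusted p of 0.264, 0.354 and 0.533). B-lineage with T-cell genes had rho = -0.0962 in the 74 arrays of the larger T-cell cluster (adjusted p = 0.449).

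Genes that followed the cell-cycle score were next examined, to see which other genes marked samples with more cell-cycle transcripts. Of 8 pre-B receptor genes 3 rose, 1 fell and 4 were not past (3 rose and 1 fell when adjusted over the list alone, adjusted p = 0.471 with an estimated correlation). IGLL1 rose by 0.95 (SE 0.20, adjusted p = 0.000179) on the log2 scale per SD of the score, VPREB3 by 0.87 and TCL1A by 0.76, whereas LYN fell by 0.305. BLNK, an adaptor of B-cell receptor signalling in the B-lineage list, rose by 0.78. PCLAF, a PCNA-binding protein of replication forks, rose by 0.84 (SE 0.08, adjusted p = 1.06e-12), IGFBP7 by 0.78, SCCPDH by 0.75 and RPA3, a subunit of the single-strand DNA-binding complex, by 0.70. LMNA, which encodes lamin A/C of the nuclear envelope, fell by 1.02 (SE 0.14, adjusted p = 6.62e-08). EMP1 fell by 0.88, SH3BP5 by 0.83, the kinase gene SGK1 by 0.80, the phosphatase gene DUSP5 by 0.73, TCF7L2 by 0.70, and the nuclear receptor gene NR4A3 and the stress-response gene NDRG1 by 0.67 each. In all, 1065 of 3566 genes were past limma's threshold, 549 rising and 516 falling, and 100 shuffled scores gave at most 2. Scores of random lists were not tested, so how far the count is particular to cell-cycle genes cannot be told.

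By list, 3 of 9 tubulin genes rose with the cell-cycle score, none fell and 6 were not past (3 when adjusted over the list alone): TUBA1B by 0.40 (SE 0.04), TUBB by 0.38 (SE 0.05) and TUBA1C by 0.22 (SE 0.04). Of 11 microtubule-associated genes 6 rose, none fell and 5 were not past (6 rose and 1 fell when adjusted over the list alone), led by STMN1 with 0.47 (SE 0.08, adjusted p = 2.82e-06). Among targets of other drugs, 4 of 9 rose and none fell (6 adjusted over the list alone), among them ATIC of purine synthesis (0.56) and TOP2B, a topoisomerase (0.38). In the apoptosis list BID rose by 0.30, whereas MCL1 fell by 0.37, TNFRSF10B by 0.32 and BIRC2 by 0.17, with 9 of 13 not past (1 rose and 3 fell adjusted over the list alone). Immediate early genes fell in 6 of 26 cases and rose in none (4 fell adjusted over the list alone), and the stem and progenitor list had CD44 and CD69 falling by 0.42 and 0.49 with 4 not past (2 fell adjusted over the list alone). None of the 30 ribosomal, 10 interferon and 7 red-cell genes was past (0 adjusted over the list alone in each). Camera called no list along this score at this setting, and the smallest adjusted p with an estimated correlation, 0.285 for the targets of other drugs, was not stable (0.002925 to 0.766 over 13 alternatives). Over all genes 1065 of 3566 were past along this score, so the counts of the tubulin, apoptosis and stem and progenitor lists lie near the general share. In the arrays of lower and higher scale factor alone, 649 and 267 genes were past.

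The pre-B receptor score marked samples with more B-lineage transcripts. CD79B rose by 0.52 (SE 0.10, adjusted p = 0.000185) per SD of the score, CD79A by 0.45, POU2AF1, a B-cell coactivator, by 0.56 and the kinase gene BLK by 0.73. In total, 8 of 11 B-lineage genes rose and none fell, and 11 rose when adjusted over the list alone. Camera called the list with an adjusted p = 0.000509 with an estimated correlation (1.97e-05 to 0.0613 over 13 alternatives, the highest in the arrays of lower scale factor). Lymphoid progenitor genes rose in 5 of 8 cases, 5 also when adjusted over the list alone, with MME at 0.58, DNTT at 0.54, CD9 at 0.74 and LEF1 at 0.63; that list had an adjusted p = 0.210 with an estimated correlation. Of 15 cell-cycle genes 6 rose, none fell and 9 were not past (11 rose adjusted over the list alone), TYMS by 0.42 and MKI67 by 0.19, with an adjusted p = 0.359 with an estimated correlation.

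CXCL8, CEBPB and several immediate early genes ran the other way. CXCL8 fell by 0.92 (SE 0.20, adjusted p = 0.000833) per SD of the pre-B receptor score, CEBPB, a transcription factor of myeloid and inflammatory genes, by 0.82, TLE3 by 0.72, NR4A3 by 0.68, IER3 by 0.64, LMNA by 0.63, EMP1 by 0.61 and NR4A2 by 0.59. Of 26 immediate early genes 7 fell, none rose and 19 were not past (8 fell adjusted over the list alone), with an adjusted p = 0.251 with an estimated correlation. Rising genes outside the lists were IGFBP7 (0.88), EIPR1 (0.72), CLEC11A (0.68) and IGLL3P (0.71), a pseudogene of the IGLL family whose signal cannot be separated from that of its relatives; BLNK rose by 0.64. In the tubulin list TUBB and TUBA1B rose by 0.19 and 0.18 and 7 members were not past (2 rose adjusted over the list alone), while the list's median slope was -0.05, its mean -0.01 and camera's direction upward with an adjusted p = 0.863 with an estimated correlation. Over all 3573 genes 522 were past limma's threshold, 354 rising and 168 falling, against at most 3 in 100 shuffled scores. Within the arrays of lower and higher scale factor the counts were 138 and 72.

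Along the stem and progenitor score, PDE4B, a phosphodiesterase, rose by 0.77 (SE 0.14, adjusted p = 0.00024) per SD of the score, the homeobox gene HLX by 0.76, SH3BP5 by 0.76, LSP1, an actin-binding protein of leukocytes, by 0.73, EMP1 by 0.72, CYTIP by 0.72, the granule proteoglycan gene SRGN by 0.71 and FOSL2 by 0.70. NRN1 fell by 0.82 (SE 0.20, adjusted p = 0.00794), TCFL5 by 0.63, ID3, an inhibitor of E-protein transcription factors, by 0.63, CSF2RB by 0.60, MTCL1 by 0.54, NUP62 by 0.53, CRMP1 by 0.50 and the cell-cycle regulator E2F1 by 0.49. STMN1 fell by 0.43 (SE 0.08, adjusted p = 0.000294), the only one of 11 microtubule-associated genes past the threshold (1 adjusted over the list alone, adjusted p = 0.279 with an estimated correlation). TUBB and TUBA1B fell by 0.21 and 0.18 with 7 of 9 tubulin genes not past (4 fell adjusted over the list alone, adjusted p = 0.359 with an estimated correlation).

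Red-cell genes rose with the same score in 2 of 7 cases, ALAS2 of haem synthesis by 0.67 and HBD by 0.66, and 5 rose when adjusted over the list alone (adjusted p = 0.359 with an estimated correlation). Interferon genes rose in 2 of 10 cases, IRF7 by 0.41 and BST2 by 0.33, and 6 when adjusted over the list alone (adjusted p = 0.279 with an estimated correlation). The survival genes MCL1 and BCL2 rose by 0.28 and 0.26 with 11 of 13 apoptosis genes not past (2 rose adjusted over the list alone). NUSAP1 and RRM2 of the cell-cycle list fell by 0.30 and 0.37 with 13 members not past (5 fell adjusted over the list alone, adjusted p = 0.359 with an estimated correlation). Of 3575 genes 223 were past limma's threshold, 101 rising and 122 falling, and shuffled scores gave at most 1. The counts were 55 and 5 in the arrays of lower and higher scale factor, and 32 without the minimum on the mean value.

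Along the tubulin score, the histone genes H3C8 (0.54, SE 0.12, adjusted p = 0.00667), H2AC14 (0.48), H2AX (0.44) and H2BC9 (0.43) rose, as did RRM2, a subunit of ribonucleotide reductase (0.50), the centromere gene CENPN (0.47), PRC1 of the spindle midzone (0.46) and the antiproliferative gene BTG3 (0.52). Near-identical copies make single histone genes uncertain. ARID5B fell by 0.56 (SE 0.14, adjusted p = 0.0221), the histone demethylase gene KDM4B by 0.41, POU4F1 by 0.37, PIKFYVE and OGT by 0.36 each, CSGALNACT1 by 0.35, ENTPD4 by 0.34 and ME2 by 0.32. Of 15 cell-cycle genes 3 rose, MCM7 by 0.28, PCNA by 0.32 and RRM2, none fell and 12 were not past (7 rose adjusted over the list alone, adjusted p = 0.448 with an estimated correlation). ACTB, JUND and DNAJB1 rose by 0.14, 0.13 and 0.32 as single members of the actin, immediate early and heat-shock lists.

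Few genes followed the tubulin score, and their number moved with the setting. Limma called 86 of 3572 genes, 42 rising and 44 falling, against at most 6 in 100 shuffled scores, but 42 genes (27 rising and 15 falling) after quantile normalization, 4 without probe sets that can match several transcripts, and 3 and 0 in the arrays of lower and higher scale factor.

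Of 31 genes linked to particular subtypes of B-lineage leukaemia, 18 had at least 1 array in an upper tail. The 7 that were measured spread no more than matched random lists (median excess 0.00, adjusted p = 0.935). CCN2, a matricellular growth factor gene, exceeded both 4 times its median and a signal of 1000 in 16 of 75 arrays (21.3%, 95% Wilson interval 13.6% to 31.9%), and TCFL5 and SH3BP5 did in 12 each (16%, 9.40% to 25.9%). CHST2 did so in 10 arrays, STAP1 in 9, NID2 in 8 and BIRC7, CLIC5, CD27, PTPRM and PTPRK in 5 each, while KANK1 and CCNA1 reached it in 4, MEIS1, CRLF2 and IGF2BP2 in 2 and MUC4 and ARPP21 in 1. The 13 genes with none allow a share of up to 4.87% past both limits. Of them WNT16, CSPG4, PCLO and NRXN3 exceeded 4 times their median but stayed under 1000. ETV6 and IKZF1 are also among the 13, but they are linked to the disease by fusion or deletion, so an empty upper tail tells nothing of them. The counts and their order depended on the setting: at 8 times the median STAP1 had 8 arrays, TCFL5, CHST2 and NID2 7 each, PTPRM 5, PTPRK 4, CCN2 3, BIRC7 and CD27 1 each, and SH3BP5, CLIC5 and ARPP21 0. With the mean of all probe sets of a gene, SH3BP5 had 7 and CLIC5 2, and SH3BP5 had 9 without the 3 arrays of background above 60.

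The first principal component held 10.96% of the variance (jackknife SE 1.19), with its highest mean loadings in the pre-B receptor, cell-cycle and B-lineage lists. The second held 8.54%, led by the subtype-linked and lymphoid progenitor lists, the next components 6.20% and 5.64%, both led by red-cell genes, and the last one examined 4.13%, led by T-cell genes. These leads moved with the setting. In the arrays of higher scale factor the subtype-linked list led the first component and the pre-B receptor list the second, at a minimum of 1000 the red-cell list had 3 measured members and led neither component 3 nor 4, and without 1 array that had high T-cell genes, plasma-cell genes led the last one examined. Correlation with log2 scale factor was not past the threshold for any of these components, and was largest for the second (absolute r = 0.246, permutation p = 0.0342; absolute rho = 0.236, permutation p = 0.042, adjusted p = 0.210). Without the minimum on the mean value, components 2 and 3 were past it (absolute rho = 0.422 and 0.363, adjusted p = 0.0006 and 0.00375; 0.0006 to 0.976 and 0.00375 to 0.899 over the 11 alternatives that did not remove scale factor).

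Genes on the same chromosome rose and fell together. Mean pairwise rho exceeded every one of 1000 matched random lists for all 22 autosomes (adjusted p = 0.001, the smallest they can give). The highest were chromosome 21 with 0.122 over 43 genes, chromosome 14 with 0.0996 over 128, chromosome 18 with 0.0961 over 59, chromosome 4 with 0.0896 over 106 and chromosome 10 with 0.0746 over 139, and the lowest chromosome 1 with 0.0232 over 367. Without the minimum on the mean value, chromosome 5 was no longer past the threshold (adjusted p = 0.209; 0.001 to 0.209 over 13 alternatives), which left 21.

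**Figure D4:**
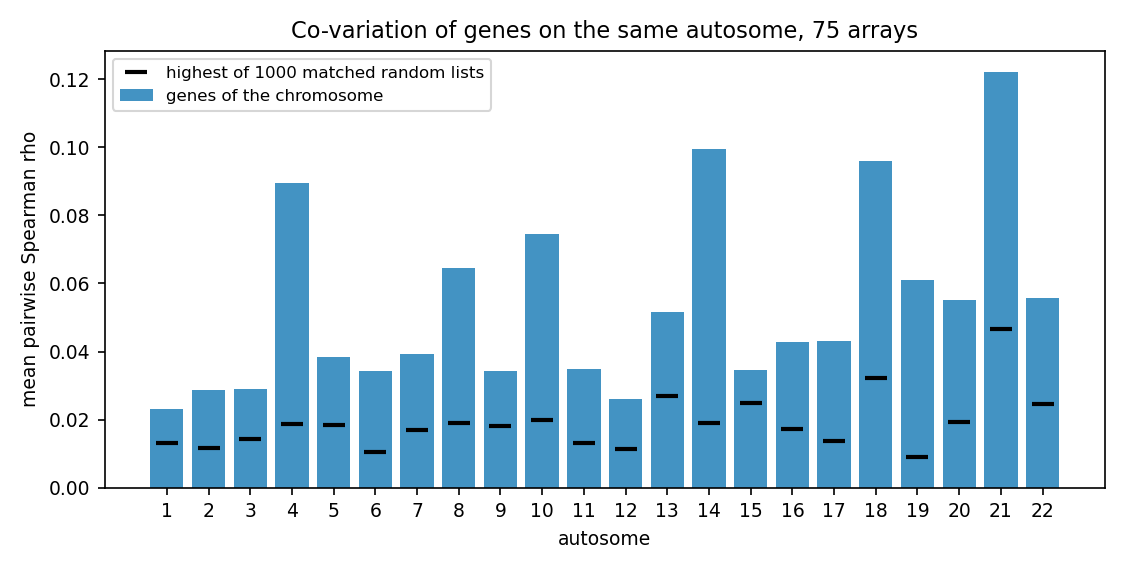
Mean pairwise Spearman rho over the 75 arrays of the measured genes of each autosome (bars), with the highest of 1000 matched random lists (black marks). Chromosomes 21, 14, 18 and 4 stand highest, at 0.122, 0.0996, 0.0961 and 0.0896, and every bar lies above its mark.

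Few lists and genes varied with array brightness. Of 44 relations of list scores with log2 scale factor or the GAPDH ratio, 1 was past the threshold: targets of other drugs were lower at higher scale factor (r = -0.349, permutation p = 0.00195; rho = -0.406, permutation p = 0.0004, adjusted p = 0.0176; r = -0.362 without the 2 farthest arrays). Within the arrays of lower and higher scale factor, rho was -0.287 (permutation p = 0.0836) and -0.145 (permutation p = 0.386). Limma called 144 of 5653 probe sets along log2 scale factor, 82 higher and 62 lower, and 47 (33 higher and 14 lower) after quantile normalization. The smallest p-values, chosen after their values were seen, belonged to HUWE1 (slope 0.35, SE 0.04, adjusted p = 4.89e-09), EEF1A1 (0.30), TPT1 (0.32), RPL41 (0.30) and JUND (0.31). All of these are probe sets that can match several transcripts, so the genes behind their signal are uncertain. Without probe sets of that kind, limma called 9 of 2212. Further ribosomal protein genes were called and higher at higher scale factor, among them RPL39, RPS23 and RPS12 (0.26 each, also chosen afterwards). The ribosomal protein score itself was not past the threshold.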

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

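The alternative that leaves out 1 array was chosen after seeing the data; all others were planned. Over all alternatives, 647 values of named genes kept direction and side of the threshold and 110 ended below it, 30 of them in the arrays of lower and 37 in those of higher scale factor, where fewer arrays were tested. For lists 240 were the same, 17 weaker, 4 stronger and 13 reversed, and for relations 136, 11, 8 and 3. Without the minimum on the mean value, hypervariable genes numbered 282, genes associated with scale factor 225, with the stem and progenitor score 32 and with the tubulin score 16, list pair relations past the threshold 7 and technical relations 4, and the first principal component held 5.41%. With a mean of at least 1000, fewer genes were tested, and 546 followed the cell-cycle and 46 the tubulin score, with 0 technical relations and 12.3% for the first component. The threshold of 8 times the median lowered upper-tail counts, for CCN2 to 3 and for SH3BP5 to 0. Quantile normalization gave 47 genes for scale factor and 42 for the tubulin score. In the arrays of lower scale factor the counts were 0 for scale factor, 649, 138, 55 and 3 for the cell-cycle, pre-B receptor, stem and progenitor and tubulin scores, 0 relations and 0 technical relations, with 14.4% for the first component; in those of higher scale factor 0, 267, 72, 5 and 0, with 0 technical relations. Fewer arrays were tested there. Without _s_at and _x_at probe sets, which removes many genes, 9 genes followed scale factor and 511, 242 and 4 the cell-cycle, pre-B receptor and tubulin scores, with 9 lists past co-variation, 6 past spread, 1 relation and 2 technical relations. Mean rho changed sign for apoptosis (0.127 at the minimum of 1000, 0.0312 at higher scale factor), cholesterol synthesis (-0.0155 at the minimum of 1000, -0.00156 with both covariates, -0.0192 at lower scale factor, -0.00765 without _s_at and _x_at, -0.00302 without the 1 array), drug transport (0.0191 with no minimum, 0.0401 at lower scale factor), subtype-linked genes (0.0332 with no minimum, 0.0379 without _s_at and _x_at) and, without _s_at and _x_at, microtubule-associated (-0.0973) and tubulin genes (-0.0862). B-lineage with T-cell genes turned to 0.0782 with no minimum and 0.194 at higher scale factor, and tubulin with drug transport to 0.00162 with no minimum. Beyond fewer arrays or genes, the cause was not tested. The stem and progenitor score could not be computed at the minimum of 1000 or without _s_at and _x_at probe sets, where it had too few members. The list test with a preset correlation called 0, 7, 7 and 4 lists along the cell-cycle, pre-B receptor, stem and progenitor and tubulin scores against 0, 1, 0 and 0 with an estimated one. No paired analysis was possible because the samples form a single group, and their numbers only name them. Low signal limits dim genes. At the median scale factor the minimum of 500 stands for 12.75 units before scaling, with a median noise of 1.38.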

Other observations

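Of the tests below, the one on the CD1 genes and the one of chromosomes with array brightness removed were chosen only after the result was seen. A condition and an interval, each named where used, were not part of the rules set beforehand.

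Genes of blood cells other than lymphoblasts rose together in 3 relations. Without the minimum on the mean value, where all 27 lists could be tested, T-cell genes rose with monocyte genes (r = 0.495, permutation p = 1e-05, the smallest the permutations can give; rho = 0.489, permutation p = 4e-05, adjusted p = 0.00036 over 18 relations; r = 0.572 without the 2 farthest) and with natural killer genes (r = 0.481, permutation p = 2e-05; rho = 0.390, permutation p = 0.00069, adjusted p = 0.00311; r = 0.481 without the 2 farthest) in 74 arrays. Monocyte and neutrophil granule genes rose together in the 71 arrays of the larger cluster (r = 0.521, permutation p = 1e-05; rho = 0.431, permutation p = 0.00026, adjusted p = 0.00156; r = 0.422 without the 2 farthest), whereas rho was 0.190 for red-cell with neutrophil genes and 0.179 for B-lineage with monocyte genes (adjusted p = 0.175 for both). In the arrays of lower scale factor, T-cell with monocyte genes had r = 0.527 (permutation p = 0.00097) and rho = 0.529 (adjusted p = 0.0057), T-cell with natural killer genes r = 0.5205 (permutation p = 0.00098) and rho = 0.437 (adjusted p = 0.0214), and monocyte with neutrophil genes r = 0.4415 (permutation p = 0.00942) and rho = 0.357 (adjusted p = 0.0787). At higher scale factor the same relations had r = 0.388 (permutation p = 0.0169) and rho = 0.193 (adjusted p = 0.251), r = 0.394 (permutation p = 0.0147) and rho = 0.235 (adjusted p = 0.194), and r = 0.455 (permutation p = 0.00476) and rho = 0.280 (adjusted p = 0.141). S100A8, a calprotectin subunit of myeloid cells, had a mean signal of 3063 ± 9041, NKG7 of cytotoxic granules 987 ± 877, MPO, myeloperoxidase, 666 ± 1369 and GNG11 of the platelet list 814 ± 1047 (SD, n = 75). Most members of these lists lay under the minimum: it held for 4 of 13 T-cell, 1 of 12 natural killer, 3 of 16 monocyte and 1 of 15 neutrophil granule genes. In this setting the natural killer and monocyte scores also rose with the GAPDH ratio (rho = 0.338 and 0.343, adjusted p = 0.0436 for both), and principal components 2 and 3 followed scale factor (absolute rho = 0.422 and 0.363), so RNA integrity and array brightness stay open for the 3 relations.

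Drug-related genes of the fixed lists were also measured. NR3C1, the glucocorticoid receptor, had a mean signal of 4089 ± 1512 and TSC22D3, a gene that glucocorticoids induce, 32320 ± 13050. MCL1 had 14070 ± 7432, BCL2 519 ± 274 and PMAIP1 7764 ± 4635. JUND, an immediate early gene, had a lowest signal of 23840 over the 75 arrays.

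In 1 array, 9 of 10 T-cell genes examined lay above every other array, GATA3 being the exception, and 5 of 7 B-lineage genes lay below every other array, with CD24 and BLNK inside the range. CD3D had a signal of 14340 against a median of 360.4 and a highest value of 1269 in the other 74 arrays, and CD79B 101 against a lowest value of 372. Among 7 T-lineage genes named before the test, 5 lay above every other array, which met the limit set beforehand for T-lineage leukaemia cells. PTCRA, of immature T cells, and LCK did not, but each lay above 98.65% of the other arrays. Mature T cells also express most of the 5. A condition outside that limit was therefore applied, that PTCRA and CD1B both exceed every other array. PTCRA did not, and with this condition the test did not decide for T-lineage leukaemia cells. Mature blood T cells lack the thymic genes CD1A, CD1B and CD1E, and 3 of 3 lay above every other array, which argues against blood T cells as the whole source. The test set beforehand for blood T cells expected the lower of the DNTT and RAG1 percentiles to be under 10. It was 12.2, which by that rule spoke against them. A 95% Wilson interval, not part of the rule, ran from 6.53 to 21.5 and held 10, so the test is treated as undecided. That interval covers counting over the other 74 arrays only, not the error of the 1 array's own signal. The design names no second kind of leukaemia, an exchanged sample stays open, and leaving the array out moved no count of genes by over 1.5 times.

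Co-variation along chromosomes was weighed against neighbourhood and brightness. For pairs over 20 measured genes apart, 22 of 22 autosomes still lay above 200 random lists, which argues against neighbouring genes as the only source, and with scale factor and GAPDH ratio removed 22 autosomes stayed past the threshold, which argues against brightness or RNA integrity. Scores of chromosomes 4, 6, 10, 14, 17, 18 and 21, which are commonly gained together in hyperdiploid leukaemia, had a mean rho of 0.446 with each other, against a median of 0.113 and a 95th percentile of 0.246 over all 170544 choices of 7 autosomes. Only 8 choices (0.00469%) were as high, in line with joint gains in part of the samples. No karyotype was analysed here, and no biological group of the design could be tested.

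Heat-shock genes formed 2 sets of arrays, 65 and 10, with the component means 4.93 SD apart. With no minimum on the mean value the larger set held 67 arrays. The 2 sets were not found without probe sets that can match several transcripts, which are 8 of the 10 members, so signal shared between related genes stays open. HSPA6, a strictly inducible member, had a mean signal of 1010 ± 4259 and a highest value of 35980, and HSPH1 had 1648 ± 2367. With scale factor and GAPDH ratio removed the list still varied together, with a mean rho of 0.293 (adjusted p = 0.000314). That argues against array brightness or RNA integrity as the cause of the co-variation. The test covered all arrays at once, so it cannot decide the cause of the 2 sets. With the same measures removed, the relation of immediate early with heat-shock genes was again computed within a larger cluster of 65 arrays. No biological explanation was tested, and handling of the samples before RNA extraction stays open.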
